A study of Mus musculus with 6 samples.

How the data were processed

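RNA was sequenced from mouse haematopoietic stem cells that had been sorted from bone marrow and kept in culture with UNC0638, an inhibitor of the histone H3K9 methyltransferases G9a and GLP (genes Ehmt2 and Ehmt1), or with its solvent DMSO. Per the labels, the cells came from adult C57BL/6 mice aged 8 to 12 weeks and were sorted as Kit-positive, lineage-negative, Sca-1-positive, Flk2-negative and CD150-positive. They were grown for 5 days in X-VIVO15 medium with 25 ng/ml stem cell factor and 5 ng/ml thrombopoietin. The labels give 2 doses of UNC0638, 0.3 µM in the protocol and 1 µM in the treatment field, and it was not possible to tell which one applied. RNA was isolated with Trizol, and libraries were built from 1 µg of total RNA with the Illumina TruSeq RNA kit. The labels list 6 libraries in 2 groups, 3 with DMSO and 3 with UNC0638. Nothing in the labels says whether the 3 libraries of a group came from separate mice, sorts or cultures. The authors' DESeq p-values therefore measure only the spread between these libraries, which may be partly technical. The binomial, Fisher's and permutation tests below count genes, which are not independent replicates, and measure no spread between libraries.

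Per the submitters' processing notes, the reads were processed with TopHat, TopHat2, Bowtie2, SAMtools, bedtools and DESeq and the genome build mm9. The versions of these tools, their order and the gene annotation were not given in the sources used here. The file used here is the authors' own comparison of the groups by DESeq and holds 784 entries for 776 gene symbols. Every entry has an adjusted p under 0.1, so genes that did not come near the threshold were not analysed here. Per the file headers, the signal columns are mean normalized read counts over all libraries, over the DMSO libraries and over the UNC0638 libraries. The authors' fold change is the ratio of the UNC0638 mean to the DMSO mean, and the deposited log2 fold change is its logarithm. The p-value columns deposited by the authors hold DESeq's p and its adjusted p. Multiplying each adjusted p by its rank and dividing by the unadjusted p gave 18083 genes as the number the authors had adjusted over. The test planned before the data were examined assumed values per library where these exist. As the table holds group means, the authors' DESeq p-values were used for the comparison.

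A gene was taken as changed at an adjusted p under 0.05 from the authors' DESeq test. The direction of all changed genes was compared with an even split by a two-sided exact binomial test. A total of 23 gene lists were written before the data were examined. They cover markers of haematopoietic and other cell types, haematopoietic transcription factors, surface antigens of the sort, H3K9 methylation enzymes, germline genes, imprinted genes, neuronal genes, adhesion genes, and genes of the cell cycle, the p53 response, the interferon response, inflammatory signalling, lipid synthesis and the lysosome. Older symbols were matched through RefSeq's gene table of GRCm38.p6, which matched 751 of the 776 symbols. That assembly differs from mm9, so no coordinates are given. Some lists hold an older and a current symbol of the same gene, such as Jhdm1d and Kdm7a. The list sizes given below count symbols, so they can count a gene more than once and understate the share that changed. For each list with at least 5 changed members, the numbers of higher and lower members were compared with those of all other changed genes by a two-sided Fisher's exact test. A symbol with several entries counted once, by the entry with the highest mean. Benjamini-Hochberg adjustment covered the 12 lists tested. A list member without an entry either did not reach an adjusted p of 0.1 or was not tested by the authors, and the table does not tell these apart. For the same reason a count adjusted over the list alone could not be computed.

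Genes named in the text followed a rule fixed before the data were examined. It took the 6 largest rises and the 6 largest falls among changed genes with a mean normalized count of at least 50, up to 4 changed genes of each list by adjusted p, Ehmt1, Ehmt2 and 6 surface antigens of the sort or its neighbouring gates where listed, and the gene with the smallest adjusted p in each direction. Other list members, and genes named for their values in single libraries, were chosen after their values were seen.

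A group mean of normalized counts is a sum of whole reads of 3 libraries, each read being worth a fixed amount that depends on its library's size factor. These 3 amounts per group were searched for in the 16 lowest means. The amounts found wrote 16 of 16 means of each group as whole reads to the precision of the table. The next best amounts wrote 12 for DMSO and 11 for UNC0638. With them, each group mean up to 160 was decomposed into the whole reads of its libraries, and a mean was kept where exactly 1 decomposition fitted. A mean was dropped all the same where slightly shifted values of it found more than 1 decomposition on average. The libraries of a group were called a, b and c in order of decreasing size factor. These letters carry no replicate number, and nothing in the labels ties a letter in one group to the same letter in the other. Size factors were 1.03, 1.00 and 0.917 for DMSO libraries a, b and c, and 1.43, 1.17 and 0.960 for UNC0638 libraries a, b and c. Total reads per library cannot be had from the table. Tested on simulated data of the same 784 genes, the procedure returned the right reads for 229 of 229 DMSO means and 405 of 405 UNC0638 means that it resolved. In the deposited data, 327 genes were resolved in both groups, 267 of them with an adjusted p under 0.05 by the authors' DESeq test and a mean of at most 102. A further 119 changed genes were resolved in 1 group only, 83 in DMSO and 36 in UNC0638, and 264 in neither. For genes resolved in 1 group, folds without a library of that group were taken against the mean of the other group in the authors' deposited table. With 3 libraries against 3, an exact permutation test cannot give a p under 0.1, so recovered values are described by their spread and by whether the groups overlap.

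Alternatives were other thresholds on adjusted p (0.1 and 0.01), a minimum change of 2-fold, minimum means of 10 and 50, leaving out genes with a group mean of 0, 1 entry per symbol, Benjamini-Hochberg and Bonferroni adjustment over the entries of the table, a pseudocount of 5 on group means, and folds recentred on the ratio of the summed group means. Leaving out each recovered library in turn was added after the data were seen. The list test and the test of neighbouring genes were tested on simulated data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.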

Results

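Expression was compared between haematopoietic stem cells cultured for 5 days with UNC0638 and with DMSO, 3 libraries each. The comparison asks which transcripts differ when G9a and GLP, which methylate histone H3 at lysine 9, are inhibited during culture of these cells. Unless a sentence speaks of recovered reads, levels are the authors' mean normalized counts per group, and folds are those of UNC0638 over DMSO in the authors' deposited table.

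With UNC0638, the changed genes of the mast cell, erythroid and megakaryocyte lists were mostly higher, and those of the stem cell, interferon response and imprinted lists mostly lower, as counted and tested below. The largest rises in the authors' deposited table, by the fixed rule, were those of Slc45a3, at 9.51-fold, Hnf4a, a nuclear receptor best known from liver, at 8.52-fold, and Atp1a3, a sodium pump subunit, at 7.90-fold. Afp, the fetal serum protein alpha-fetoprotein, rose 7.07-fold, the IgE receptor chain gene Fcer1a rose 6.96-fold and the coagulation factor gene F13a1 rose 6.86-fold in the same comparison of the authors' deposited table. The largest falls there were those of 2410018L13Rik, 8.43-fold lower, Bcam, a laminin receptor, 8.07-fold lower, and Serpinh1, a collagen chaperone, 7.30-fold lower. Nrk, Fscn1, which bundles actin, and Sdc4, a heparan sulfate proteoglycan, were 5.49-fold, 5.00-fold and 4.95-fold lower in the authors' deposited table. In recovered reads, leaving out DMSO library a brought Serpinh1 to 3.76-fold, Fscn1 to 2.91-fold and Sdc4 to 3.16-fold lower, and leaving out UNC0638 library b brought Nrk to 8.86-fold lower. Against the DMSO mean of the authors' deposited table, Bcam was 12.3-fold lower without UNC0638 library b. The smallest adjusted p values by DESeq in the authors' deposited table were 1.99e-30 for Hnf4a (kgCluster15315), whose mean normalized count went from 36.7 to 312.7, and 6.34e-21 for Bcam (kgCluster22183), whose mean went from 213.6 to 26.5. No value was listed for Ehmt1, Ehmt2, Kit, Slamf1, Cd34 or Cd48.

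In the authors' deposited table, 650 genes passed an adjusted p of 0.05 by DESeq, which is 3.59% of the 18083 genes tested. Of these, 273 were higher and 377, or 58.0%, were lower with UNC0638, and this split differed from an even one (two-sided exact binomial p = 5.17e-05). The binomial test counts genes, which are not independent, so it only describes the genes that passed. Among genes with an adjusted p under 0.01 by DESeq, 53.5% were lower and the split no longer differed from an even one (exact binomial p = 0.152, range over the alternatives 2.84e-05 to 0.152). Changes of at least 2-fold were found for 208 higher and 268 lower genes, and changes of at least 8-fold for 13 higher and 28 lower genes of the authors' deposited table. The median log2 fold change there was 1.51 for higher genes and -1.27 for lower genes. A further 134 genes, 60 higher and 74 lower, had an adjusted p between 0.05 and 0.1 by the authors' DESeq test.

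**Figure D1:**
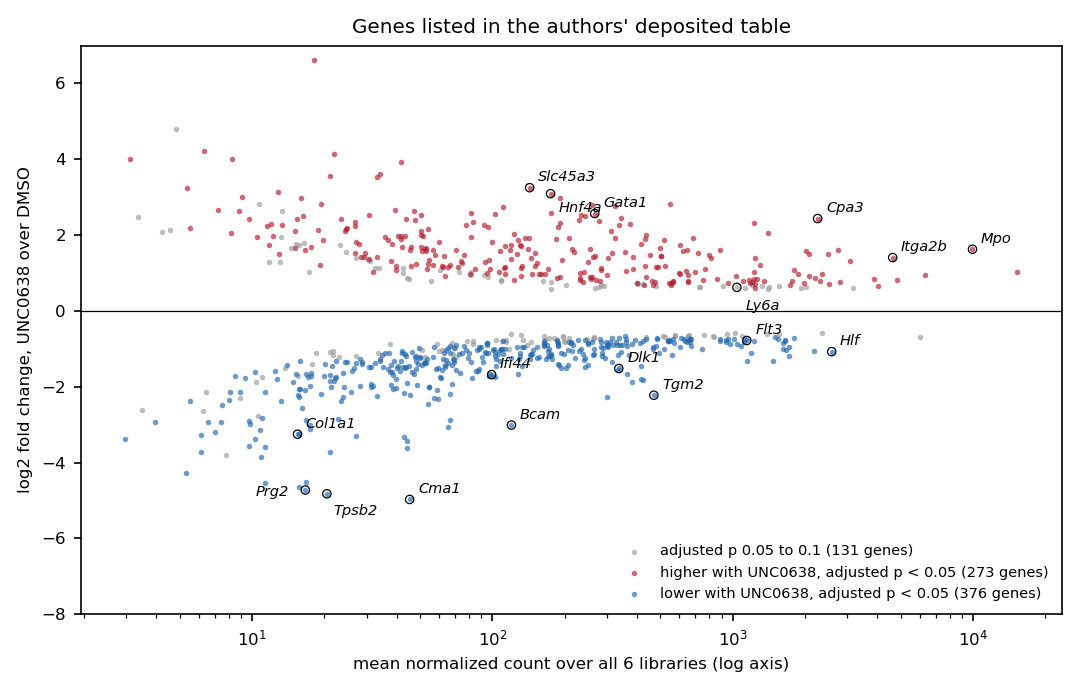
Log2 fold change (UNC0638 over DMSO) against the mean normalized count over all libraries (log axis) for each gene in the authors' deposited table, with 4 entries that have a group mean of 0 not drawn. Red and blue points passed an adjusted p of 0.05 by DESeq, grey points lie between 0.05 and 0.1, and circles mark genes named in the text.

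Of the mast cell and basophil list, 15 of 30 genes changed, 12 upward and 3 downward, a larger share upward than among the other changed genes (Fisher's exact test, adjusted p = 0.0239). Cpa3, the mast cell carboxypeptidase, rose 5.41-fold from a mean normalized count of 704.1 to 3809, and Il1rl1, the interleukin 33 receptor, rose 5.51-fold in the authors' deposited table. Slc45a3 and Fcer1a, named above, belong to this list too. Other granule protease genes of the list, Gzmb, Ctsg and Mcpt8, rose 4.95-fold, 2.84-fold and 1.51-fold in the authors' deposited table. The 3 members that fell also encode proteases stored in mast cell or basophil granules: in the authors' deposited table the log2 fold change was -4.97 for Cma1, -4.83 for Tpsb2 and -1.82 for Prss34. Without DMSO library a, Il1rl1 was 9.71-fold higher by the UNC0638 mean of the authors' deposited table. Cma1 had 12, 0 and 0 recovered reads in the UNC0638 libraries, so without UNC0638 library a it was at 0 in that group. The reads of Tpsb2 could be recovered in both groups and lay mostly in 1 DMSO library, with 10, 0 and 100 reads in DMSO libraries a, b and c against 6, 0 and 0 with UNC0638. Without DMSO library c it was 3.47-fold lower, and without UNC0638 library a it was at 0 in the UNC0638 group. By the same exact test, the list's call ended at an adjusted p under 0.01 (p = 0.138) and for changes of at least 2-fold (p = 0.0700), with adjusted p from 0.00947 to 0.138 over the alternatives. Of the eosinophil list, 3 of 13 genes changed, too few for a test: Siglec5 and Il5ra rose 5.25-fold and 4.47-fold, and Prg2, the granule major basic protein, was 26.5-fold lower in the authors' deposited table. Recovered reads of Prg2 were 1, 30 and 60 in the DMSO libraries and 1, 1 and 2 in the UNC0638 libraries. It was 12.7-fold lower without DMSO library c and 41.3-fold lower without UNC0638 library c, and Il5ra was 2.28-fold higher without UNC0638 library a and 6.84-fold higher without DMSO library c.

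Genes of the granulocyte list changed in both directions, 10 of 34 upward and 5 downward (Fisher's exact test, adjusted p = 0.0986). In the authors' deposited table the granule protein genes Elane and Mpo rose 3.72-fold and 3.09-fold, and Mpo reached a mean normalized count of 15033 from 4869. Ms4a3 and the collagenase gene Mmp8 rose 3.80-fold and 4.80-fold in the authors' deposited table. Mmp8 had 62, 13 and 7 recovered reads in the DMSO libraries, and without DMSO library a it was 12.5-fold higher by the UNC0638 mean of the authors' deposited table. The chemoattractant receptor genes Cxcr2 and Ltb4r1 rose too, with log2 fold changes of 0.98 and 1.25 in the authors' deposited table. The 5 members that fell, Ltf, S100a9, S100a8, Lcn2 and Padi4, had log2 fold changes of -1.61, -1.71, -1.62, -1.10 and -0.70 in the authors' deposited table. All but Padi4, whose reads were not recovered, had over 66.7% of their recovered DMSO signal in 1 library, a for Ltf and Lcn2 and c for S100a8 and S100a9, and in none of them did the libraries of the groups separate. Without that library Ltf, S100a9 and S100a8 were 1.06-fold, 1.22-fold and 1.36-fold lower and the direction of Lcn2 turned. When library a of both groups was left out, Lcn2 kept its direction. Lcn2 was also 48.8-fold lower without UNC0638 library a and 1.43-fold lower without UNC0638 library b. Of the monocyte, macrophage and dendritic cell list, 12 of 46 genes changed, 9 upward and 3 downward (Fisher's exact test, adjusted p = 0.0596). F13a1 was followed by the integrin gene Itgax, at 4.48-fold, the chemokine receptor gene Ccr2, at 4.08-fold, and Mpeg1, at 3.28-fold, in the authors' deposited table. Without DMSO library b, Itgax was 6.99-fold higher by the UNC0638 mean of the authors' deposited table.

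Of the erythroid list, 10 of 45 genes changed, 9 upward and 1 downward (Fisher's exact test, adjusted p = 0.0198). Gata1, the transcription factor needed for red cell and megakaryocyte maturation, rose 5.93-fold, and Spna1, the alpha-spectrin gene of red cells, rose 5.13-fold in the authors' deposited table. Ces2g rose 3.76-fold and the beta-globin gene Hbb-b1 rose 2.97-fold in the authors' deposited table, and the water channel gene Aqp1 was the member that fell (log2 fold change -1.20). The changed beta-globin genes Hbb-b1 and Beta-s are near-identical copies that can share reads, so their separate values are uncertain. Spna1 had 23, 193 and 53 recovered reads in the DMSO libraries, and without DMSO library b it was 11.6-fold higher by the UNC0638 mean of the authors' deposited table. The 3 members with reads recovered in both groups were Klf1, Rhag and Car1, and the groups' libraries separated for Klf1 and Rhag. Rhag was 4.22-fold higher without DMSO library c, and Car1 was 2.36-fold higher without UNC0638 library c and at 0 in the DMSO group without DMSO library b. With a minimum mean of 50 the call ended (Fisher's exact test, adjusted p = 0.0952, range over the alternatives 0.00791 to 0.0952). The megakaryocyte and platelet list had 8 of 38 genes changed, 7 upward and 1 downward (Fisher's exact test, adjusted p = 0.0358). Itga2b (CD41) rose 2.65-fold to a mean of 6729, Sdpr rose 3.27-fold and Mfsd2b rose 2.29-fold, while the thrombospondin gene Thbs1 was 2.67-fold lower in the authors' deposited table. By the same exact test this call ended at an adjusted p under 0.01 (p = 0.142), for changes of at least 2-fold (p = 0.144) and with a minimum mean of 50 (p = 0.0590), with adjusted p from 0.0125 to 0.144 over the alternatives.

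Of the stem cell and multipotent progenitor list, 12 of 42 genes changed, 11 of them downward (Fisher's exact test, adjusted p = 0.0405). Tgm2 was 4.67-fold lower, Ndn, an imprinted gene expressed in quiescent stem cells, was 3.17-fold lower, Robo4 was 2.43-fold lower, and Hlf, a stem cell transcription factor, was 2.11-fold lower, from a mean of 3503 to 1663, in the authors' deposited table. Gata2 was the member that rose (log2 fold change 0.65 in the authors' deposited table). The call ended when genes with an adjusted p up to 0.1 were added (Fisher's exact test, adjusted p = 0.0569, range over the alternatives 0.0229 to 0.0569). Among surface antigens of the sort and of progenitor gates, 5 of 29 changed, 3 upward and 2 downward (Fisher's exact test, adjusted p = 0.705). Itga2b and the myeloid integrin gene Itgam (CD11b, 2.85-fold) rose, while Procr (CD201) and Flt3, the gene of the Flk2 antigen absent from the sorted cells, were 2.0-fold and 1.72-fold lower in the authors' deposited table. Ly6a, the gene of Sca-1, had a log2 fold change of 0.62 and did not pass (adjusted p = 0.0608 by DESeq in the authors' deposited table). Haematopoietic transcription factors went both ways, 7 of 60 upward and 4 downward (Fisher's exact test, adjusted p = 0.291). After Gata1, the smallest adjusted p values were those of Cebpe, a granulocyte factor, at 3.85-fold, Zbtb16, at 2.73-fold, and Hlf, in the authors' deposited table. The recovered groups overlapped for Cebpe, which was 1.99-fold higher without UNC0638 library a and 7.98-fold higher without DMSO library a.

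**Figure D2:**
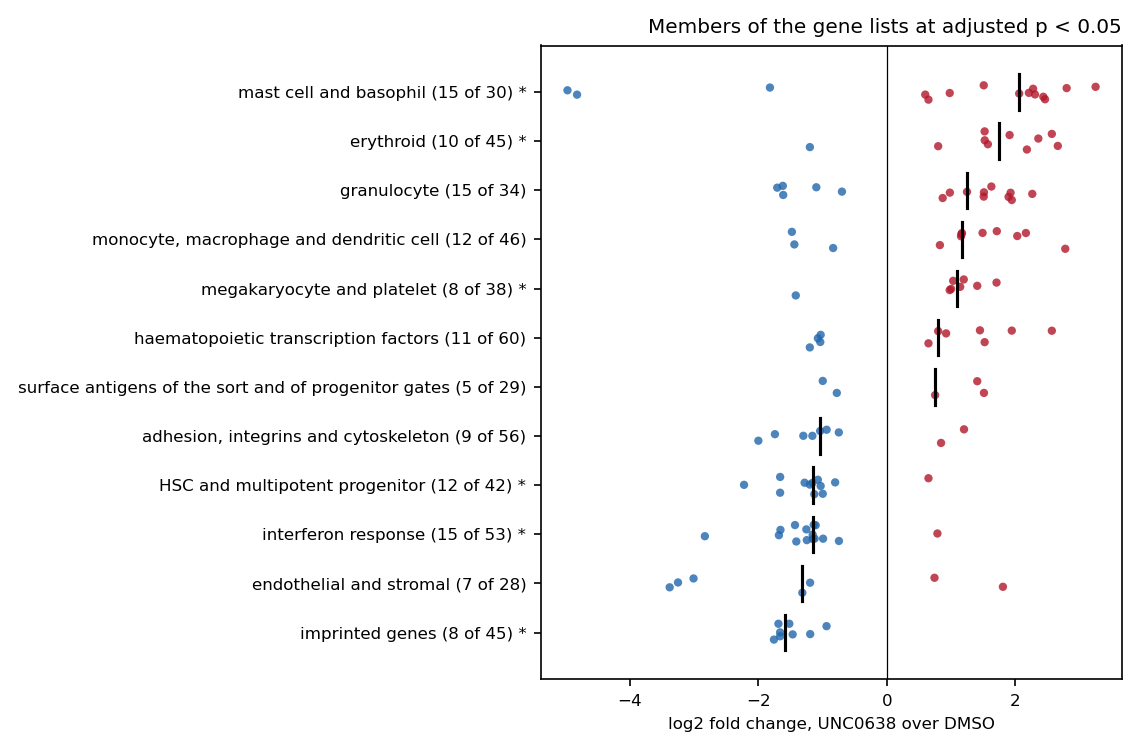
Log2 fold change (UNC0638 over DMSO, authors' deposited table) of each changed member of the 12 gene lists with at least 5 changed genes, 1 point per gene, with a bar at the list's median. Brackets give changed genes and list size, and asterisks mark the 6 lists whose direction differed from the other changed genes at an adjusted p under 0.05 by Fisher's exact test.

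Changed interferon response genes were mostly lower: of 53 in the list, 14 were lower and 1, Ifi47, was higher (Fisher's exact test, adjusted p = 0.0198). In the authors' deposited table Mpa2l, a guanylate-binding protein gene, was 7.13-fold lower, Ifi44 was 3.21-fold lower, Irf7, a transcription factor that drives interferon genes, was 2.66-fold lower, and Oas3, which senses double-stranded RNA, was 2.37-fold lower. For Ifi44, 18, 52 and 81 reads were recovered in the UNC0638 libraries, and without UNC0638 library c it was 5.29-fold lower by the DMSO mean of the authors' deposited table. Reads could be recovered in both groups for 4 members, Mpa2l, Ifit1, Ifit3 and Zbp1. DMSO library c held a median of 2.80 times their mean over all 6 libraries, against 0.948 and 0.722 in DMSO libraries a and b, and the groups' libraries separated for 1 of the 4. Without DMSO library c, Mpa2l, Ifit1, Ifit3 and Zbp1 were 3.64-fold, 1.35-fold, 1.57-fold and 1.68-fold lower, and without UNC0638 library b Ifit3 and Zbp1 were 5.26-fold and 4.52-fold lower. Of 43 inflammatory cytokine and chemokine genes, 4 changed, all downward. They were the cytokine signalling inhibitors Socs2, Socs3 and Cish, at 2.0-fold, 2.11-fold and 1.95-fold lower, and the cytokine gene Il18, 2.19-fold lower in the authors' deposited table. Socs3 had 306, 53 and 61 recovered reads in the DMSO libraries and 120, 84 and 40 in the UNC0638 libraries, and its direction turned without DMSO library a. Without library a of both groups Socs3 kept its direction, but libraries b and c overlapped. They held 52.8 and 66.5 normalized counts with DMSO and 72.1 and 41.7 with UNC0638.

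Imprinted genes that changed were all lower, 8 of 45 in the list (Fisher's exact test, adjusted p = 0.0474). In the authors' deposited table, Rian and Dlk1, which lie in the same imprinted cluster as Meg3, were 3.38-fold and 2.87-fold lower, and Meg3 and Ndn were 3.22-fold and 3.17-fold lower. In the higher of its entries, Meg3 had 153, 12 and 15 recovered reads in the DMSO libraries against 27, 20 and 18 with UNC0638, and its direction turned without DMSO library a. Cdkn1c, an imprinted cell cycle inhibitor, had 71.7 ± 17.8 recovered normalized counts with DMSO and 22.6 ± 7.90 with UNC0638 (SD, n = 3 each), with no overlap between the groups. Ndn and Cdkn1c belong to both the imprinted and the stem cell list. Genes of one cluster are not independent, so the list's test rests on fewer separate loci than the 8 genes it counts. In the same exact test the imprinted list's call ended for changes of at least 2-fold (p = 0.0538) and with a minimum mean of 50 (p = 0.102), with adjusted p from 0.0310 to 0.102 over the alternatives.

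In the remaining lists few genes changed, or the members went both ways. Among the genes named from them, Col1a1, Sparc, Igll1, Ddx4 and Celsr3 each had over 66.7% of the recovered signal of their higher group in 1 library. Without it, Col1a1, Sparc and Ddx4 were 1.57-fold, 3.05-fold and 1.60-fold lower, and Igll1 and Celsr3 were 3.31-fold and 1.20-fold higher. Without DMSO library a, Igll1 and Celsr3 were 14.8-fold and 4.59-fold higher and Plk2 was 1.62-fold lower. Of 28 endothelial and stromal genes, 2 were higher and 5 lower (Fisher's exact test, adjusted p = 0.705). Col1a1 and Sparc were 9.53-fold and 8.06-fold lower, and the basement membrane collagen genes Col4a2 and Col4a1 were 2.49-fold and 2.29-fold lower in the authors' deposited table. Recovered reads of Col1a1 were 5, 75 and 4 in the DMSO libraries and 2, 5 and 3 in the UNC0638 libraries. Of 56 adhesion, integrin and cytoskeleton genes, 2 rose and 7 fell (Fisher's exact test, adjusted p = 0.377), among them Jam3, Itga3 and Esam, 3.35-fold, 4.0-fold and 2.24-fold lower, and Itgal, 2.30-fold higher, in the authors' deposited table. Of 24 B cell genes, Igll1 and Bank1 rose, and of 30 T cell and NK cell genes, Nkg7, Lck and Cd5 rose, with log2 fold changes of 2.99, 2.10, 1.40, 0.84 and 1.98 in the authors' deposited table. Of 68 genes on the list of germline genes silenced in somatic cells, none rose at this threshold and 3 fell. Ddx4, Stag3 and Tex15 were 3.58-fold, 2.04-fold and 2.53-fold lower in the authors' deposited table. These 3 were not silent with DMSO, where their mean normalized counts were 34.2, 135.4 and 35.7. Gpc2, whose span overlaps that of Stag3, also fell, so reads of these genes may be shared. Another list member, Tdrd9, was listed at 0 with DMSO and above 0 with UNC0638 and did not pass. None of 40 listed symbols of the H3K9 methylation machinery passed the authors' DESeq test at an adjusted p of 0.05. Of 61 cell cycle genes, Cdkn1c alone passed. Of 34 p53 target and DNA damage genes, Perp and Gadd45a rose 2.10-fold and 1.73-fold and Plk2 was 2.62-fold lower in the authors' deposited table. The cholesterol and fatty acid list of 39 genes had 1 changed member, Abca1, which exports cholesterol and rose 3.85-fold, and the lysosome list of 43 had 1, Ctss, which was 1.79-fold lower in the authors' deposited table. Without DMSO library c, Abca1 was 9.0-fold higher by the UNC0638 mean of the authors' deposited table. Of 44 neuronal genes, Celsr3 rose 2.48-fold and Uchl1 was 2.77-fold lower in the authors' deposited table.

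Whole reads per library could be recovered in both groups for 267 changed genes of low to moderate expression, 79 higher and 188 lower with UNC0638. For 173 of them, 64.8%, the 3 libraries of one group all lay above the 3 of the other, where chance would give 10%. That chance holds for genes not selected on these libraries, while these genes had been selected by the authors' test, so the difference is no test of change. Uchl1 had 64.5 ± 4.90 recovered normalized counts with DMSO and 23.3 ± 8.21 with UNC0638, and Bank1 had 5.71 ± 1.23 and 24.5 ± 3.17 (SD, n = 3 each). For 57 of the 267 genes, 15 higher and 42 lower, over 66.7% of the signal of the higher group came from 1 library. Sprr2a1, of a family of near-identical genes and listed here in 3 entries, had in the highest of them 251, 1 and 0 reads in DMSO libraries a, b and c and 27, 0 and 1 with UNC0638, and Cox6a2 had 23, 3 and 1 with DMSO and 192, 0 and 0 with UNC0638. Library a was the one in 34 of the 42 lower genes and in 15 of the 15 higher genes. Leaving out 1 library moved the fold by over 1.5 times for 133 of the 267 genes, or 49.8%, counting genes left at 0 in a group. Leaving out a library with 0 reads moves a fold by exactly 1.5 times, and rounding put such genes on either side of the limit. Rhag was counted and Kcnq3 was not, both at 1.5, so the count is approximate. Of the 119 changed genes with reads recovered in 1 group only, 34 moved as much when a library of that group was left out. Without DMSO library a Sprr2a1 turned its direction, and without UNC0638 library a Cox6a2 was at 0 in the UNC0638 group's remaining libraries. Without the highest library of the higher group, the fold was under 1.5 for 44 of the 267 genes.

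**Figure D3:**
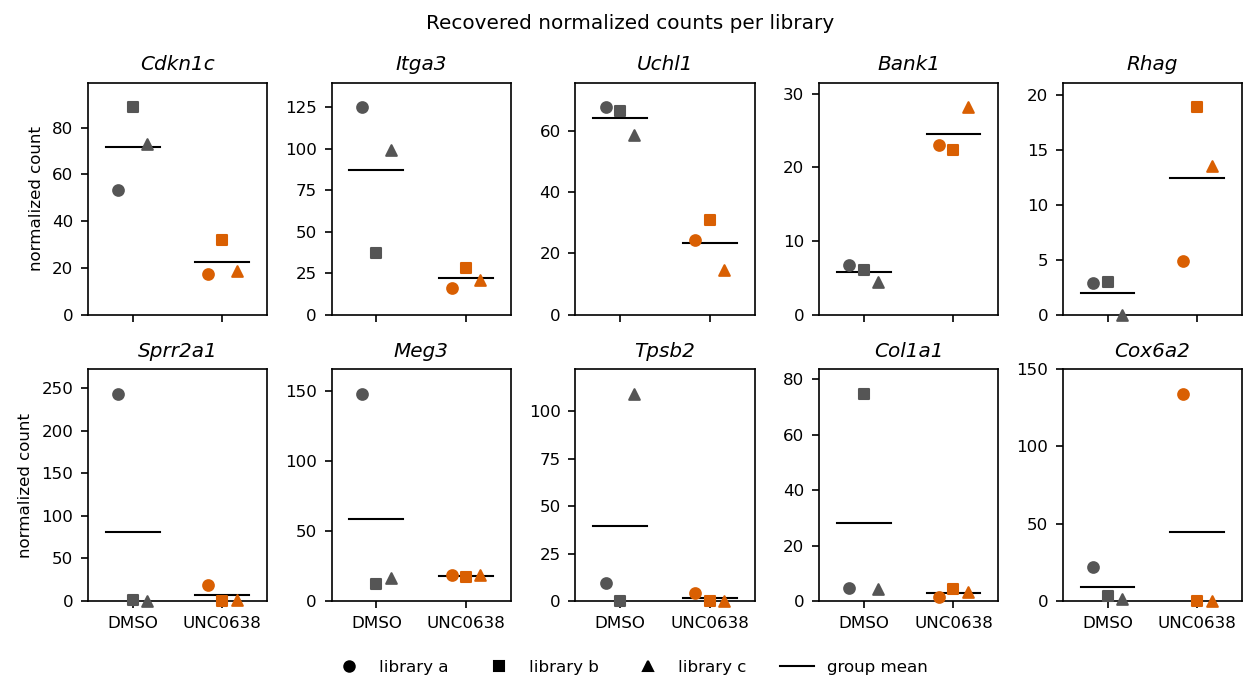
Recovered normalized counts of 10 genes, chosen after their values were seen, in DMSO and UNC0638 libraries a (circle), b (square) and c (triangle), with a bar at each group's mean. In the upper genes the groups do not overlap, and in the lower genes over 66.7% of the higher group's signal lies in 1 library.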

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

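The alternatives that leave out recovered libraries were chosen after the data were seen, as was the wider definition of neighbours; the others were fixed before. The number of changed genes stayed within 1.5 times of 650 except with Bonferroni adjustment over the table's entries, which left 361, 176 higher and 185 lower. The entries had already been selected from 18083 genes, so adjusting over them alone is too lenient and leaves too many genes. With 784 entries in all, the threshold of 0.1 and Benjamini-Hochberg adjustment over the entries had to stay within that range. Lower genes numbered 235 at an adjusted p under 0.01 and 241 with a minimum mean of 50, and made up 53.5% (exact binomial p = 0.152) and 54.3% (p = 0.0790) of changed genes there. Both settings keep fewer genes. The number of lists that passed went from 6 to 3 for changes of at least 2-fold. Upward shares in lists that no longer passed Fisher's exact test were 14.3% for stem cell genes (adjusted p under 0.1, list p = 0.0569), 75.0% for mast cell genes (under 0.01, p = 0.138, and 2-fold, p = 0.0700), 85.7% for erythroid genes (minimum mean 50, p = 0.0952), 83.3% for megakaryocyte genes (under 0.01, p = 0.142, and 2-fold, p = 0.144) and 87.5% (minimum mean 50, p = 0.0590), and 0% for imprinted genes (2-fold, p = 0.0538, and minimum mean 50, p = 0.102). These settings change both the members and the genes they are compared with, and the cause was not tested. The interferon list passed in all 7 alternatives run for it, with adjusted p from 0.0120 to 0.0361. Recentring on the ratio of the summed group means shifted log2 fold changes by 0.27, less than the smallest change among the 650 genes, 0.60, so it could turn no direction. A pseudocount of 5 on both means cannot turn one either. It was applied to the 77 genes picked by the naming rule only, and among these moved Prg2 the most, by 2.15.

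Of the 267 changed genes with reads recovered in both groups, 243 to 267 kept a fold of at least 1.5 in their direction when 1 library was left out, and 244 without library a of both groups. Leaving out DMSO library a turned the direction of 15 entries, among them Sprr2a1, Lcn2, Meg3, Cd74 and Socs3, and leaving out UNC0638 library a turned 6, among them Cox6a2, Gpr34 and Cth. Without library a of both groups, 8 entries turned, among them Sprr2a1, Meg3, Cox6a2 and Gpr34. Lcn2, Cd74, Socs3 and Cth kept their direction there. The counts of changed genes and the list tests could not be repeated without a library, since 383 of the 650 changed genes stay pooled in at least 1 group. No paired analysis was possible because the deposited columns are group means and the recovered libraries carry no replicate number. The alternatives that need counts per sample, namely DESeq2, a filter on low counts and pseudocounts per sample, were not run. Depth limits what the recovered genes can show, since some rest on a few reads per library, such as Rhag with 3, 3 and 0 with DMSO.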

Other observations

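All tests in this part were chosen after the results were seen, and each hypothesis was found and tested on the same data.

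Outside the lists, the genes of the coagulation factors VII and X, F7 and F10, which lie side by side, rose with log2 fold changes of 3.13 and 2.52 in the authors' deposited table. In recovered reads, F7 had 7, 0 and 1 with DMSO and 76, 5 and 11 with UNC0638, so that it was 3.0-fold higher without UNC0638 library a and 42.1-fold without DMSO library a. F10 was 3.11-fold higher without UNC0638 library a. Il22ra2, a soluble receptor for interleukin 22, had a log2 fold change of 4.14 there, and its recovered reads were 3, 2 and 2 in the DMSO libraries and 65, 26 and 55 in the UNC0638 libraries. The unnamed transcript 1700008I05Rik had 0, 0 and 1 reads with DMSO and 52, 15 and 56 with UNC0638. Pgr, the progesterone receptor gene, and Chst2, a sulfotransferase gene, had log2 fold changes of -2.04 and -3.32 in the authors' deposited table. The groups overlapped for Pgr, with 12, 126 and 50 reads against 8, 14 and 28, and it was 2.12-fold lower without DMSO library b and 7.27-fold lower without UNC0638 library c. Chst2 was 25.0-fold lower without UNC0638 library b.

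The genes that rested on 1 library were not spread evenly over the libraries. Of the 34 entries that rested on DMSO library a, 28 were also highest in UNC0638 library a, or 82.4%, against 28 of 154 other entries that fell, or 18.2% (Fisher's exact test, p = 1.77e-12). Sprr2a1 and Meg3 have several entries among the 34, and all entries were read in the same libraries and can vary together. This p therefore does not measure how often libraries of the 2 groups would match by chance. In the reverse direction, 12 of the 15 genes that rested on UNC0638 library a were highest in DMSO library a. A size factor error of DMSO library a that alone gave a share over 66.7% would lift all genes there alike by 4-fold or more. Over 162 genes that rose with UNC0638, the median log2 ratio of DMSO library a to the mean of b and c was 0.36 (quartiles -0.53 and 1.11). This argues against an error of that size. These genes had been selected as lower with DMSO, which may itself reduce their level in DMSO library a, so the test is a limited one. A smaller error that adds to other spread was not tested. A candidate explanation is that library a of both groups shared a source, such as a sort, a day or a set of mice, that differed from the rest; the labels give no such source, and which replicate number library a carries is unknown. An effect of UNC0638 on these genes stays open and was not tested. Across the 267 genes, which are not independent, deviations from the group mean correlated at r = 0.58 between library a of both groups. The 4 pairs of a DMSO and a UNC0638 library among b and c lay between 0.24 and 0.39, the highest being library c of both groups, and the 4 pairs of a library a with a library b or c between -0.50 and -0.39. Deviations sum to 0 within a group, so a match of library a alone also makes the pairs among b and c positive. The difference of library b from c, which is free of this, correlated at 0.07 between the groups. Shuffling the UNC0638 letters within each gene 1000 times gave a central 95% range of -0.15 to 0.15 for this difference and of -0.18 to 0.17 for that of library a from the other two. Each gene was shuffled on its own, so these ranges hold only for independent genes. They cannot show that library a matched beyond chance, since the genes of a library can vary together.

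Genes of the mast cell list moved apart. The granule protease genes Cpa3, Gzmb, Ctsg and Mcpt8 were among the 12 that rose, with log2 fold changes of 2.44, 2.31, 1.51 and 0.60, and Cma1, Tpsb2 and Prss34 fell, in the authors' deposited table. Mature mast cells present in 1 DMSO library may account for the fall of Tpsb2: 91.8% of its recovered DMSO signal lay in library c. For Cma1 and Prss34 this could not be examined, since Tpsb2 was the only one of the 3 whose DMSO reads could be recovered. A source in 1 library thus cannot be told apart from a fall of these 3 transcripts in all cultures. Other mast cell list members, which rose, were not confined to library c. Recovered reads in DMSO libraries a, b and c were 89, 13 and 88 for Fcer1a, 202, 19 and 92 for Il1rl1, and 32, 7 and 40 for Slc45a3. Whether mature mast cells could have been carried through the sort or have arisen during the 5 days of culture was not tested. A change in the share of mast cells and other biological explanations were not tested.

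Neighbouring genes that changed tended to change in the same direction. Of 616 changed protein-coding genes placed by RefSeq's order in GRCm38.p6, 46 pairs had no other protein-coding gene in between, and 36 of them, 78.3%, went the same way against 51.1% in permuted directions (one-sided permutation p = 0.00022, 100000 permutations). Chance order of directions is thereby an unlikely source. Examples were Cebpe and Slc7a8, Mpeg1 and Dtx4, Tmprss3 and Ubash3a, which rose, and Rcn3 and Fcgrt, Trpc6 and Pgr, which fell. Many pairs belong to one gene family or overlap, such as Col4a1 and Col4a2. Without those, 17 of 25 pairs went the same way (permutation p = 0.066), so for unrelated neighbours chance order was not excluded. Tandem gene families and overlapping genes therefore cannot be told apart from a wider effect on gene neighbourhoods. With up to 2 genes in between, 67 of 99 pairs went the same way, or 67.7% (permutation p = 0.00059), and 40 of 67, or 59.7%, without families and overlaps (p = 0.098).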
